A study of Danio rerio with 8 samples.

How the data were processed

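Gene expression was measured by RNA sequencing in cells sorted from the heart ventricles of adult zebrafish carrying the transgene Tg(-6.8wt1a:EGFP), in which a fragment upstream of the gene wt1a drives green fluorescent protein (GFP). Per the labels, the fish were 3 to 9 months old, 3 to 5 hearts were pooled per sample, and each of 4 pools gave a library of GFP-positive and a library of GFP-negative cells, 8 libraries in all. Per the labels' protocols, libraries were made from 0.2 to 0.6 ng of total RNA with a single-cell kit and 2 rounds of amplification, and were read as single reads of 60 bases. The same protocol text also names another library kit and cells carrying mCherry from the ventricular apex. The sample titles and characteristics speak of GFP alone and were used for the grouping.

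Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt (version not given in the sources used here) and RSEM 1.2.25, with genome build Zv9; the aligner and the annotation release were not given in the sources used here. The deposited values are TPM (transcript abundance corrected for transcript length and scaled to the same total in each library): each column sums to 1000000 within rounding, the values have 2 decimals, and low values show no common step. TPM keeps no sequencing depth, so the depth per library is unknown, and no interval that needs read counts was computed. The table holds 31388 gene identifiers, of which 6832 are listed at 0 in every library. Symbols were taken from a table of gene names for 25925 identifiers, and 4151 identifiers share a symbol with another, so genes are given with their identifier where this matters. Many symbols are in the human style without a paralog letter. Members of near-identical families (globins, keratins, cardiac troponin, myosin and actin paralogs) are uncertain, because reads can be split among copies.

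A count model had been planned before the data were examined; the values are not counts, so it was not used. The main test was limma 3.58.1 in R 4.3.3 on log2(scaled TPM + 1), with a prior variance that follows the mean level, pool as a block and the labelled sort as the tested term, and Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. Libraries were scaled by an unweighted trimmed mean of log ratios (30% of the ratios and 5% of the abundances trimmed at each end), over the genes with at least 1 TPM in at least 4 libraries, 13877 in number, which were also the genes tested. Input tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

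The series design text states that the replicates are paired, and the pool label gives the pairs, so the block is part of the main fit. As a check, deviations from the means of the labelled sorts were correlated across genes: same-numbered libraries had r of 0.492, 0.537, 0.446 and 0.403 for pools 1 to 4. Libraries of different numbers had similar values between pools 1 and 2 (0.474 and 0.552) and between pools 3 and 4 (0.382 and 0.437), and negative values otherwise. The highest correlation between any pair of libraries was 0.928, and no library was treated as a repeat of another.

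Before the data were examined, 22 lists of marker and pathway genes were fixed, with 848 entries. Of these, 805 (94.9%) were matched by symbol, by a RefSeq synonym (assembly GRCz12tu, used for names alone) or by the symbol without its paralog letter. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The genes named in the comparison of labelled sorts follow a rule fixed beforehand: wt1a, wt1b and tcf21 whatever their result, up to 10 called genes with the largest change in each direction at a mean of at least 10, up to 4 called members per list, and at most 2 uncalled members of highest mean level where a list had fewer than 2 called ones. TPM stood in for the depth-scaled counts of that rule, 1 uncalled member was taken per list, and as no gene was called the rule named 25 genes.

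The comparison among pools was chosen after the data were seen. It uses the same model: an F test of the pool term and the 6 contrasts between pools. Up to 4 called members per list with the smallest p were named there, 67 genes, by a rule set after the data were seen.

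Alternatives covered other scalings (median of ratios, upper quartile, library totals, and scaling without the 50 most abundant genes), no filter and a stricter filter on low values, robust variance estimation, no replicate block, a test against a fold of 2, leaving out each pool, and leaving out each library together with the block. Pseudocounts of 0.1 and 5, a prior variance without a trend and leaving out the library labelled GFP-negative of pool 3 with the block kept were added after the data were seen. The scripts were tested on simulated data with 200 changed genes, 10 times. In the comparison of labelled sorts over 13877 genes, 9.40% of changes of 1 on the log2 scale were recovered, 70.4% of changes of 2 and 96.8% of changes of 3, with 8.2 false calls per simulation (6.53% of calls). In the F test among pools, 78.0% of the genes changed by 3 in 1 pool were recovered, with 11.2 false calls per simulation. The epicardium list shifted by 1 was called in 10 of 10 simulations, beside 2 calls of other lists. The simulated noise was independent between genes, whereas the correlation estimated for this list in the data was 0.119. These simulations thus do not show how camera behaves when list members are correlated.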

Results

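The transcriptome of adult zebrafish ventricular cells was compared between cells labelled GFP-positive and cells labelled GFP-negative in the reporter line Tg(-6.8wt1a:EGFP). wt1a encodes a transcription factor of the epicardium, the outer cell layer of the heart, so the comparison asks how the cells marked by the reporter differ from the remaining ventricular cells. The 4 libraries of each labelled sort came from 4 pools of hearts, each pool giving a library of both kinds. The depth is unknown because the values are TPM. Between 12332 and 14783 genes reached 1 TPM per library. A few genes took a large part of each library: the 50 most abundant identifiers held 74.4% to 80.5% of the TPM in the libraries of pools 1 and 2 and 45.2% to 66.3% in those of pools 3 and 4. Identifiers with mitochondrial symbols held 10.3% to 14.2% in pools 1 and 2 and 2.13% to 5.06% in pools 3 and 4.

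The reporter's own gene was examined first, as a check of the labels. wt1a (listed as WT1, ENSDARG00000031420) did not follow the labelled sort. In pool 1 it stood at 2.42 TPM in the library labelled GFP-negative and 1.15 in the library labelled GFP-positive, and in pool 2 at 1.42 and 2.59. In pool 3 it stood at 106.82 in the library labelled GFP-negative and 71.26 in the library labelled GFP-positive, and in pool 4 at 44.28 and 39.51. The mean was 28.6 ± 33.5 TPM (SD, n = 4) in the libraries labelled GFP-positive and 38.7 ± 49.6 (SD, n = 4) in those labelled GFP-negative. The log2 difference, positive minus negative, was -0.10 (SE 0.31, 95% confidence interval -0.82 to 0.62; limma adjusted p = 0.974), with the higher value in the library labelled GFP-positive in 1 of 4 pools. Leaving out pool 1 turned this difference to 0.09.

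The paralog wt1b (ENSDARG00000007990) and TCF21 (ENSDARG00000036869), a transcription factor of epicardial cells and their derivatives, had the same arrangement. wt1b lay between 3.44 and 6.78 TPM in the 4 libraries of pools 1 and 2 and between 48.29 and 60.03 in those of pools 3 and 4. TCF21 lay between 1.08 and 3.43 TPM in pools 1 and 2 and between 84.30 and 211.76 in pools 3 and 4. Between the labelled sorts, wt1b differed by 0.09 (SE 0.24; limma adjusted p = 0.969) and TCF21 by 0.47 (SE 0.29; limma adjusted p = 0.858) on the log2 scale. These markers thus did not separate the labelled sorts in either direction, and they do not bear out the labels. Every direction below is that of the labelled sorts.

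**Figure D1:**
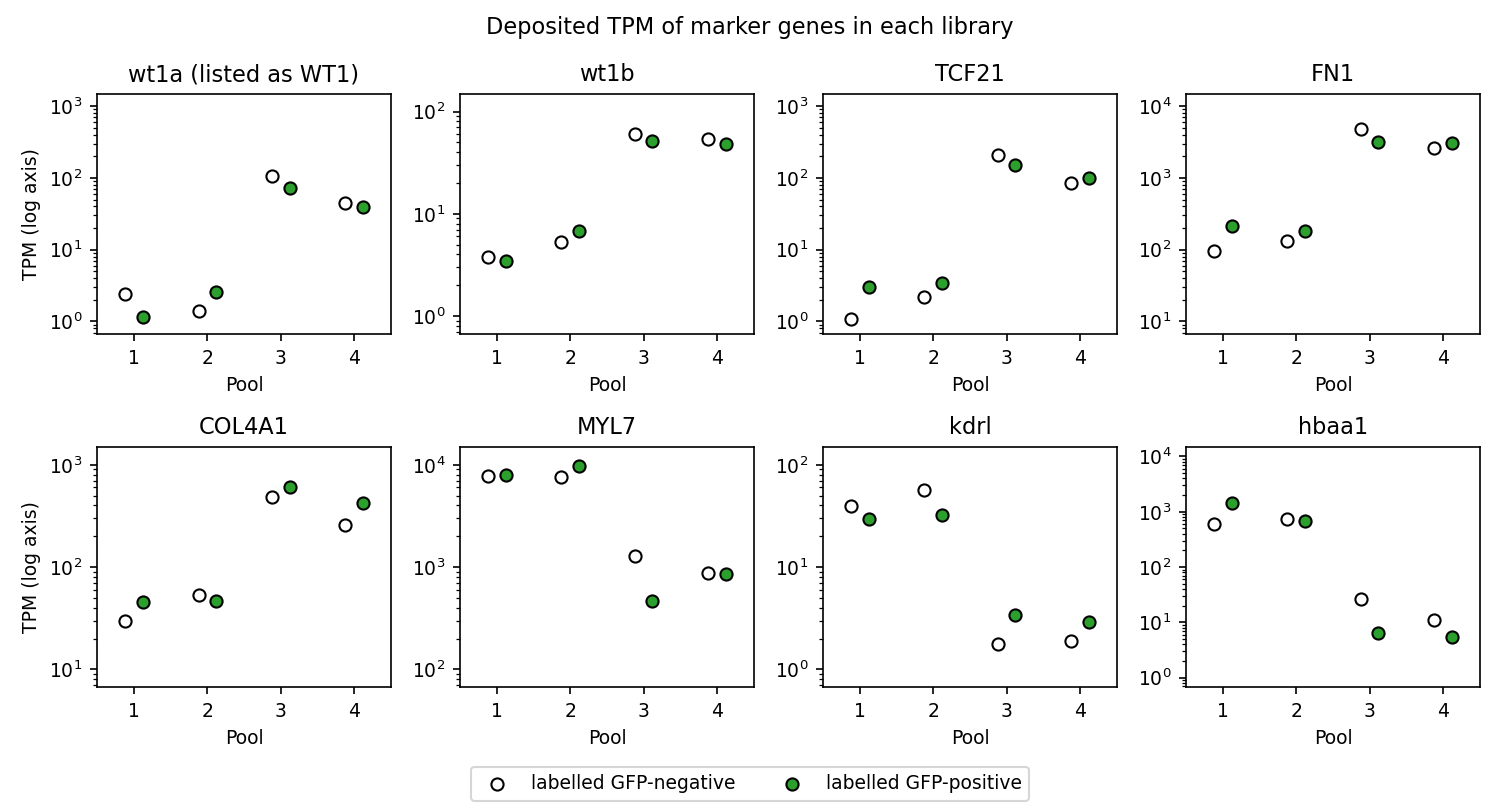
TPM on a log axis of 8 marker genes by pool, with 1 point per library, open for the library labelled GFP-negative and filled for the library labelled GFP-positive. wt1a, wt1b, TCF21, FN1 and COL4A1 are higher in both libraries of pools 3 and 4, and MYL7, kdrl and hbaa1 in both libraries of pools 1 and 2.

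No gene passed the threshold between the labelled sorts. Of 13877 genes tested, limma called 0 higher and 0 lower in the libraries labelled GFP-positive. The smallest adjusted p was 0.853. At an unadjusted p under 0.05 there were 770 genes, 392 higher and 378 lower, where 693.85 are expected by chance. The difference had the same sign in all 4 pools for 1896 genes (13.7%), where chance gives 12.5%. On simulated data with 200 changed genes, the same test recovered 96.8% of changes of 3 on the log2 scale. It recovered 70.4% of changes of 2, but 9.40% of changes of 1. With fewer changed genes the adjusted threshold is stricter, so these rates do not show how many large changes in few genes were missed. Without the replicate block limma also called 0 genes, with 327 at an unadjusted p under 0.05, and against a fold of 2 it called 0, with 37 unadjusted. Leaving out pool 2 gave 3 calls, ENSDARG00000082447, ENSDARG00000083118 and ENSDARG00000105084, and leaving out pool 3 gave 1, SOCS3 (ENSDARG00000025428), an inhibitor of cytokine signalling, at a log2 difference of 6.65 (limma adjusted p = 0.0242). These genes were named after their values were seen. Their differences with all libraries were 4.37 (SE 0.74), 5.79 (SE 1.28), 4.17 (SE 2.36) and 5.14 (SE 1.13) in the order given, each at a limma adjusted p of 0.853. Those of the first 3 without pool 2 were 5.57, 7.93 and 8.05. All 3 were listed at 0 in the libraries labelled GFP-negative of pools 1, 3 and 4 and at 73.43, 146.95 and 106.39 TPM in that of pool 2. These fitted differences thus depend on the pseudocount. SOCS3 had 0.08, 0.04, 0 and 10.64 TPM in the libraries labelled GFP-negative of pools 1 to 4 and 84.16, 175.79, 0.05 and 571.98 in those labelled GFP-positive.

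Among the 25 genes named by rule, log2 differences between the labelled sorts ran from -0.56 for CEBPB to 0.92 for THBS1, and none passed the threshold. THBS1, which encodes a matrix glycoprotein, had 49.1 ± 45.7 TPM (SD, n = 4) in the libraries labelled GFP-positive and 37.8 ± 42.2 (SD, n = 4) in those labelled GFP-negative, and was higher in the former in 4 of 4 pools (SE 0.28; limma adjusted p = 0.853). COL4A1, a chain of basement membrane collagen, differed by 0.50 (SE 0.19; limma adjusted p = 0.853), with the higher value in the library labelled GFP-positive in 4 of 4 pools after scaling but in 3 of 4 in the TPM as deposited, where pool 2 had 46.48 against 53.37. FN1, encoding fibronectin, differed by 0.46 (SE 0.27) and MYL7, a myosin light chain of cardiomyocytes, by -0.12 (SE 0.31), both short of the threshold. CEBPB, a transcription factor abundant in myeloid cells, was lower in the library labelled GFP-positive in each pool, with a mean of 114 ± 69.6 TPM (SD, n = 4) against 198 ± 137 (SD, n = 4), and did not pass either (SE 0.23; limma adjusted p = 0.853). Over the fits with a pool or a library left out, the log2 difference ran from 0.06 to 0.92 for COL4A1, from 0.43 to 1.41 for THBS1 and from -0.71 to -0.23 for CEBPB; with a pool left out and the block kept it ran from 0.41 to 0.66, from 0.64 to 1.08 and from -0.70 to -0.32.

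Of the 22 gene lists, camera called 5 between the labelled sorts at the preset correlation and 0 with an estimated correlation. Fibroblast and interstitial matrix genes lay higher in the libraries labelled GFP-positive, with a median log2 difference of 0.38 and 34 of 39 members higher (camera adjusted p = 1.39e-09; adjusted p = 0.612 with an estimated correlation). Basement membrane genes had a median of 0.28 with 15 of 17 higher (camera adjusted p = 0.000372; adjusted p = 0.612 with an estimated correlation). Epicardium genes had a median of 0.38 with 11 of 16 higher (camera adjusted p = 0.00916; adjusted p = 0.612 with an estimated correlation). Cardiomyocyte genes had a median of -0.18 with 29 of 37 lower (camera adjusted p = 0.00916; adjusted p = 0.657 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.20 with 66 of 80 lower (camera adjusted p = 8.48e-06; adjusted p = 0.652 with an estimated correlation). The list medians differed between pools: the fibroblast median was 0.96, 0.67, 0.08 and 0.21 in pools 1 to 4, and the ribosomal median 0.06, 0.11, -0.41 and -0.54.

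Adjusted over the list alone, 1 gene was called in these lists, the basement membrane gene col18a1a (ENSDARG00000036558), a collagen chain, against 0 over all genes tested. It had 67.4 ± 78.7 TPM (SD, n = 4) in the libraries labelled GFP-positive and 39.0 ± 49.1 (SD, n = 4) in those labelled GFP-negative, a log2 difference of 1.23 (SE 0.25) seen in 4 of 4 pools (limma adjusted p = 0.0244 over the list alone and 0.853 over all genes). Without the replicate block camera called 2 lists, the fibroblast and ribosomal ones; the adjusted p was 0.260 for the epicardium, 0.338 for the basement membrane and 0.620 for the cardiomyocyte list. The epicardium call was lost without pool 1 (adjusted p = 0.106) and without pool 2 (0.325), the ribosomal call without pool 4 (0.0776), and the cardiomyocyte list turned direction without pool 3 (0.75) and without the library labelled GFP-negative of pool 3 alone (0.755). fry called 0 lists for a shift in 1 direction and 2 for change in either direction, the basement membrane list (adjusted p = 0.0283) and the list of immediate early and heat shock genes (adjusted p = 0.0114). The other 17 lists had camera adjusted p between 0.0800 and 0.796. Of these, the keratin list was called, lower in the libraries labelled GFP-positive, with the TPM as deposited (adjusted p = 0.0483) and without pool 1 (0.00989), and 2 were called, higher, with a pool left out: the transcription factor list without pool 4 (0.0450) and the oxidative phosphorylation list without pool 3 (0.00325). For the immediate early and heat shock list the median was -0.00 and the mean 0.12, so that they differ in sign. This list holds SOCS3 (ENSDARG00000025428), whose log2 difference of 5.14 (SE 1.13) weighs more on the mean than on the median.

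The comparison among pools was made after this arrangement had been seen, with pool as the labels give it. Genes of cardiomyocytes, endothelium, erythrocytes and mitochondrial respiration were higher in both libraries of pools 1 and 2, and genes of fibroblasts, the extracellular matrix and part of the epicardium list were higher in both libraries of pools 3 and 4. The spread in the F test and in the contrasts between pools came from the 2 libraries of each pool. Per the labels these came from the same hearts. The p-values, and the calls counted from them below, thus do not measure variation between sets of hearts. The F test among the 4 pools called 1787 of 13877 genes (12.9%). Of these, 1090 had their highest pool means in pools 1 and 2 and 631 in pools 3 and 4, where 16.7% are expected for any given pair of pools, and 66 had another order. Limma called 1731 genes between pools 3 and 1 (644 higher in pool 3, 1087 lower), 1505 between pools 4 and 1 (577 higher in pool 4, 928 lower), 1906 between pools 3 and 2 (719 higher in pool 3, 1187 lower) and 1730 between pools 4 and 2 (671 higher in pool 4, 1059 lower). It called 0 genes between pools 2 and 1, with 375 at an unadjusted p under 0.05, and 0 between pools 4 and 3, with 1186. With the TPM as deposited, scaled to library totals, the split turned to 4729 higher and 588 lower between pools 3 and 1, to 1942 and 462 between pools 4 and 1, to 3716 and 723 between pools 3 and 2, and to 1414 and 588 between pools 4 and 2, because the median of all genes then shifted by 0.51 to 1.13 on the log2 scale. Without the library labelled GFP-negative of pool 3, which stood apart on the second principal component, the F test called 1367 genes, and the calls were 906 between pools 3 and 1 and 1149 between pools 3 and 2. The directions of the lists given below held under each of the 4 scalings unless stated.

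**Figure D2:**
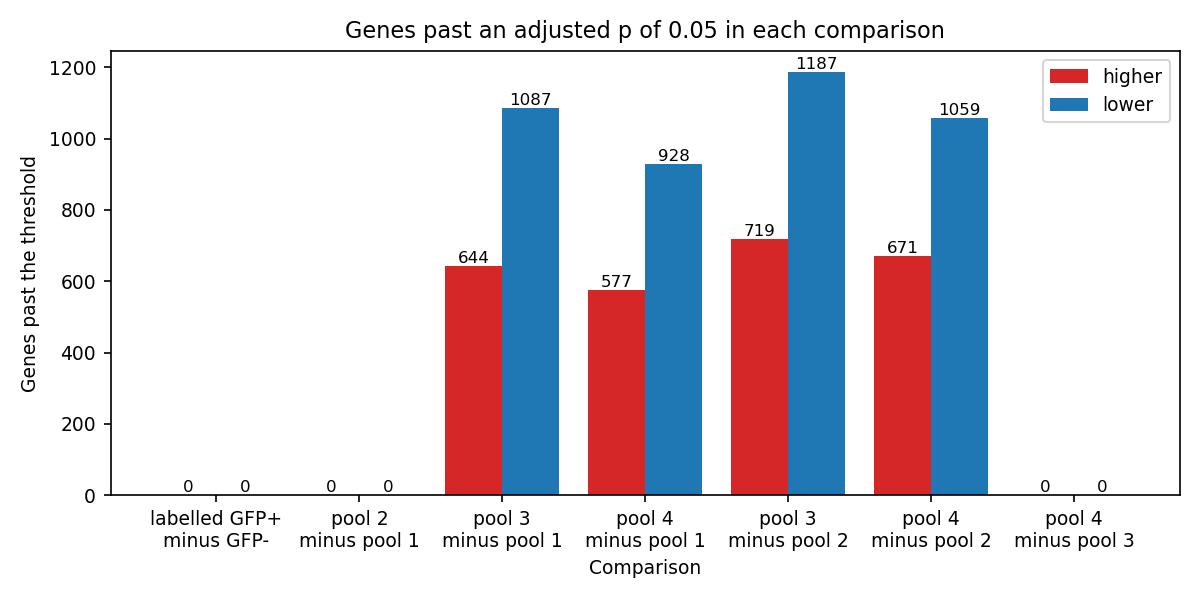
Number of genes past an adjusted p of 0.05 (limma) that were higher (red) or lower (blue), for the labelled sorts and for each contrast between pools. Bars stand at 0 for the labelled sorts, for pool 2 minus pool 1 and for pool 4 minus pool 3, and between 577 and 1187 for the other 4 contrasts.

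Of 37 cardiomyocyte genes tested, 36 differed among the pools, 35 of them with the highest means in pools 1 and 2. The myoglobin gene mb had 5147 to 8910 TPM in the 4 libraries of pools 1 and 2 and 462 to 769 in those of pools 3 and 4. The troponin gene tnnc1a had 648 to 1286 and 65.5 to 101 TPM. Among 76 genes of oxidative phosphorylation and the citrate cycle 61 differed, 60 in this direction (38 differed with the TPM as deposited), as in IDH2 with 429 to 599 against 84.8 to 114 TPM. The share of TPM in mitochondrial symbols, 10.3% or more in pools 1 and 2 and at most 5.06% in pools 3 and 4, moved with both lists. Of 37 genes of endothelium and endocardium 26 differed, all 26 highest in pools 1 and 2. The vascular growth factor receptor kdrl had 29.4 to 56.9 TPM against 1.78 to 3.42, and the endothelial cadherin cdh5 had 59.4 to 97.3 against 4.68 to 16.8. Of 16 erythrocyte genes 8 differed, all 8 in this direction; the globin gene hbaa1, uncertain because of near-identical copies, had 604 to 1458 TPM against 5.46 to 26.6.

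Fibroblast and interstitial matrix genes went the other way, with 27 of 39 called and 26 of these highest in pools 3 and 4. The matrix protein gene SPARC had 30.6 to 53.8 TPM in pools 1 and 2 and 741 to 1578 in pools 3 and 4, and DPT, encoding dermatopontin, had 7.68 to 25.2 and 638 to 1116. Of 17 basement membrane genes 11 differed, all 11 in this direction, as in the laminin gene lamc1 with 17.0 to 21.8 against 165 to 400 TPM. Of 28 matrix remodelling genes 14 differed, 13 in this direction; the collagen-modifying enzyme gene PLOD2 had 16.5 to 21.7 against 133 to 313 TPM. Among 12 complement genes 5 differed, all 5 in this direction, as in c7a with 19.6 to 33.3 against 180 to 368 TPM, and among 21 smooth muscle and pericyte genes 9 differed, 7 in this direction, as in TAGLN with 37.3 to 66.5 against 399 to 611 TPM.

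The epicardium list was mixed. Of 16 members 11 differed, 8 highest in pools 3 and 4, wt1a and TCF21 among them, and 3 highest in pools 1 and 2. Of the latter, podxl, encoding a surface sialomucin, had 99.9 to 174 TPM in pools 1 and 2 and 14.7 to 33.3 in pools 3 and 4. ALDH1A2, which encodes an enzyme that makes retinoic acid, had 38.3 to 125 and 1.60 to 5.55 TPM. Among 18 retinoic acid genes 7 differed, 6 highest in pools 3 and 4, such as the retinol carrier RBP4 with 144 to 316 against 3137 to 5726 TPM. Among 48 heart and mesoderm transcription factors 15 differed, 9 highest in pools 3 and 4, as in TBX18 with 1.33 to 4.55 against 35.4 to 90.1 TPM, and 6 in pools 1 and 2. Secreted factors were divided, with 11 of 42 called, 5 highest in each pair of pools and 1 in another order: the midkine gene MDK had 29.9 to 42.6 against 641 to 1451 TPM, and nppc, a natriuretic peptide gene, 152 to 1073 against 14.0 to 41.0.

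Of 26 macrophage and myeloid genes 5 differed, 4 highest in pools 1 and 2, while IRF8, a transcription factor of myeloid cells, had 4.03 to 8.27 TPM there and 62.2 to 150 in pools 3 and 4. Called members numbered 4 of 9 for thrombocytes, 3 of them highest in pools 1 and 2, and 2 of 9 for lymphocytes, both highest there. They numbered 2 of 6 for neutrophils, 1 highest in each pair of pools. For neural and Schwann cells they numbered 2 of 9, and for immediate early and heat shock genes 9 of 49. The log2 list median of pools 3 and 4 against pools 1 and 2 was -1.68 to -1.24 for macrophages. It was -1.95 to -1.50 for lymphocytes and -0.31 to 0.17 for neutrophils. For thrombocytes it was -1.56 to -0.56, but reached 0.20 with the TPM as deposited. Without the library labelled GFP-negative of pool 3, both neutrophil genes, nccrp1 (limma adjusted p = 0.144) and LECT2 (ENSDARG00000033227; 0.122), were no longer called, nor were the thrombocyte genes f13a1b (0.0526) and FERMT3 (0.117). Of the immediate early and heat shock genes, egr1 had 63.4 to 87.2 TPM in pools 1 and 2 and 500 to 965 in pools 3 and 4, and hsp90aa1.1 had 118 to 260 and 20.2 to 63.5. None of 80 cytosolic ribosomal protein genes, 21 keratin and epithelial junction genes or 10 cell cycle genes differed among the pools. With the TPM as deposited, however, 72, 10 and 1 of them did. The keratin gene krt18b stands outside the lists and was named after the data were seen. It had 30.8 to 56.4 TPM in pools 1 and 2 and 409 to 929 in pools 3 and 4. Numbers called also moved by over 1.5 times with the TPM as deposited for immediate early and heat shock genes (35 of 49), heart and mesoderm transcription factors (26 of 48), matrix remodelling genes (23 of 28), secreted factors (19 of 42), retinoic acid genes (13 of 18) and neural and Schwann genes (4 of 9). Calls over all genes tested also rose with that scaling, from 1787 to 4007. The rises in these lists are thus at least in part general. With a pool left out, the F test called fewer genes in all (1068 to 1401, against 1787), and fewer genes of some lists. Outside the erythrocyte list, 12.8% of genes were called with all libraries, 7.65% without pool 1 and 7.42% without pool 2. In that list the calls were 4 of 11 without pool 1 and 5 of 12 without pool 2, but 9 of 16 without pool 4. Among retinoic acid genes they were 4 of 19 without pool 1 and 4 of 18 without pool 3. Of 25 macrophage genes 3 were called without pool 1 and 2 without pool 2, but 6 of 27 without pool 4. Thrombocytes had 2 called genes without pool 1, 2 or 3, and neural and Schwann cells 1 without any 1 pool. Lymphocytes had 1 of 6 without pool 1 and 1 of 7 without pool 2, but 3 of 10 without pool 3. No neutrophil gene was called without pool 1, 2 or 3, and 1 without pool 4.

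The share of called genes in each list was set against that of all other tested genes with Fisher's exact test (two-sided), adjusted over 22 lists; genes are not independent replicates in this test. The share was in excess in 14 lists, with an adjusted p of 1.77e-39 for oxidative phosphorylation, 2.36e-30 for cardiomyocytes, 4.65e-15 for fibroblasts, 6.84e-15 for endothelium, 1.62e-06 for epicardium, 3.38e-06 for basement membrane, 7.07e-06 for matrix remodelling, 0.000896 for erythrocytes, 0.00142 for smooth muscle and for transcription factors, 0.00928 for retinoic acid, 0.0216 for complement, 0.0283 for secreted factors and 0.0296 for thrombocytes. The values of wt1a, wt1b and TCF21 had prompted the comparison among pools, and these 3 are among the called members of both the epicardium and the transcription factor list, of which 8 of 16 and 14 of 48 members also stand in another list. Without these 3 genes, 8 of 13 epicardium genes (0.000143) and 12 of 45 transcription factors (0.0213) were called. The remaining genes were measured in the same libraries in which the arrangement was seen, so this is not an independent test of it. The share was lower in the ribosomal list (8.13e-05). It passed the threshold in neither direction for 7 lists: keratin (0.137), neutrophils (0.226), immediate early and heat shock (0.343), lymphocytes (0.359), neural and Schwann cells (0.359), macrophages (0.389) and cell cycle (0.628). With the TPM as deposited, the excess was lost for erythrocytes (0.136), complement (0.162) and thrombocytes (0.329), and an excess was found for ribosomal (4.14e-29) and immediate early genes (4.54e-09). The thrombocyte excess was also lost without any 1 pool and without the library labelled GFP-negative of pool 3 (0.127 to 0.345). Of the 9 thrombocyte genes tested, 1 also stands in another list. THBS1, called in both the thrombocyte and the fibroblast list, had 3.52 to 12.33 TPM in pools 1 and 2. In pools 3 and 4 THBS1 had 50.50 to 102.16 TPM, whereas the other called thrombocyte genes were highest in pools 1 and 2. The excess of secreted factors was lost without this library (0.0796), and that of retinoic acid genes without pool 1 (0.0830) or pool 3 (0.125). An excess was found for lymphocytes without this library (4 of 7 genes, 0.00582) and for immediate early genes without this library (0.0475) or without pool 2 (0.0399).

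Whole libraries showed the same arrangement. Across the 13877 genes, which are not independent replicates, the correlation between libraries was 0.868 to 0.928 between pools 1 and 2, 0.80 to 0.83 between pools 3 and 4, and 0.645 to 0.722 between a library of pool 1 or 2 and one of pool 3 or 4. Within a pool, the correlation between the library labelled GFP-positive and the one labelled GFP-negative was 0.894, 0.902, 0.812 and 0.83 for pools 1 to 4. The first principal component held 50.4% of the variance and separated both libraries of pools 1 and 2 from both libraries of pools 3 and 4. The second held 12.0% and set the library labelled GFP-negative of pool 3 apart, at 82.7 against -45.8 to 7.03 for the others.

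**Figure D3:**
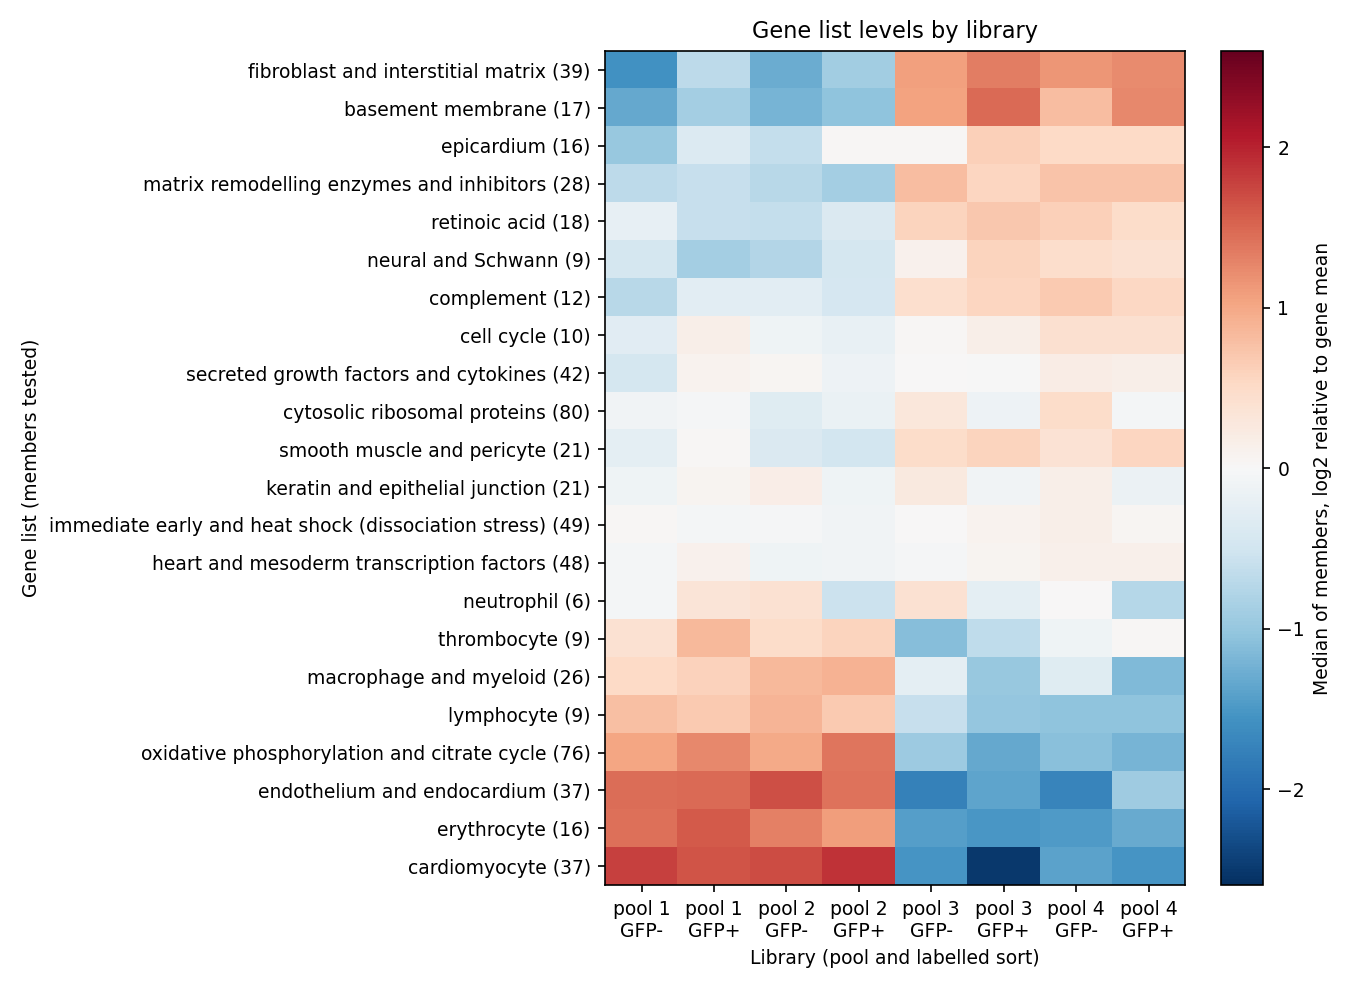
Median level of the tested members of each of 22 gene lists (rows, number of members in brackets) in each library (columns, by pool and labelled sort), as log2 relative to each gene's mean over the 8 libraries, from blue (low) to red (high). The fibroblast list runs from -1.57 to -0.69 in the libraries of pools 1 and 2 and from 1.06 to 1.32 in those of pools 3 and 4, and the cardiomyocyte list from 1.63 to 1.88 and from -2.51 to -1.40.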

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

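In 2 of 64 groups of 4 libraries, 1 library stood far from the other 3 relative to the range of the group, where chance gives about 3.2. LECT2 (ENSDARG00000090889), a secreted leukocyte factor, had 167.57 TPM in the library labelled GFP-negative of pool 3 and 7.63 to 33.29 in the others labelled GFP-negative. The share of TPM in 6 identifiers without a symbol that carry identical values in every library was 3.29% in the library labelled GFP-negative of pool 3 and 25.4% to 26.4% in the others labelled GFP-negative.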

How the results depend on the processing

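The count-based second tool and the weighted log-count model planned before the data were examined were not run, because the values are not counts. Filters, scalings, robust estimation and the test against a fold were run in their TPM equivalents; pseudocounts of 0.1 and 5, the variance without a trend, the fit without the library labelled GFP-negative of pool 3 with the block kept and all results on pools were added after the data were seen. The depth is unknown, so it could not be weighed.

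Between the labelled sorts, 0 genes were called under each alternative with all 8 libraries. Leaving out a pool or a library gave 0 to 3 calls, all higher; the 3 came without pool 2, 1 without pool 3, 1 (the same gene, SOCS3) without the library labelled GFP-negative of pool 3, and 1 without that of pool 2 and no block. Library totals shifted the median log2 difference of all genes to -0.11 and gave 199 higher and 650 lower at an unadjusted p under 0.05, where the main scaling gave 392 and 378. The named genes kept their direction in 270 results with all libraries and turned it in 5: under library totals wt1b (-0.050), SPOCK3 (-0.126), TAGLN (-0.056) and MDK (-0.080), and at a pseudocount of 5 CCR9 (0.040). With a pool left out and the block kept, 16 results turned and 84 did not; without the library labelled GFP-negative of pool 3, 7 did and 18 did not. With each library left out and the block dropped as well, as planned together, 64 turned and 136 did not; such a fit leaves a pool in 1 labelled sort alone, and its median SE was 0.807, against 0.761 with all libraries and no block and 0.240 with all libraries and the block. None of these passed the threshold (lowest adjusted p over all alternatives 0.597). Leaving out pools with the block kept, the log2 differences were -0.41 to 0.09 for wt1a, -0.06 to 0.14 for wt1b, 0.22 to 0.68 for TCF21, 0.17 to 0.72 for FN1 and -0.36 to 0.24 for MYL7. Over all of these fits, with most ends from those without the block, the ranges were -0.85 to 0.61 for wt1a, -0.35 to 0.58 for wt1b, -0.42 to 1.36 for TCF21, -0.22 to 1.15 for FN1, -0.96 to 0.91 for MYL7, -1.09 to 1.37 for SPOCK3, -0.93 to 0.11 for LECT2, -0.85 to 0.62 for CCR9, -1.84 to 1.15 for hbaa1, -0.31 to 0.57 for TAGLN, -0.53 to 0.22 for CDH2, -0.33 to 1.03 for RBP4, -0.59 to 0.75 for MDK, -0.74 to 0.47 for c6.2, -0.48 to 0.047 for zeb2a, -0.63 to 0.50 for GMNN, -0.67 to 0.17 for COX4I1, -0.10 to 0.034 for RPS2 and -0.42 to 0.22 for hsp70l.

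Of the 5 lists called, 2 were called without the replicate block, 0 with an estimated correlation and 0 by fry for a shift in 1 direction. For change in either direction, fry called the basement membrane list among them (adjusted p = 0.0283). The block changed no other call. Calls were gained for the keratin list under library totals (0.0483) and without pool 1 (0.00989), for transcription factors without pool 4 (0.0450) and for oxidative phosphorylation without pool 3 (0.00325) or its library labelled GFP-negative (0.00341). Directions turned under library totals for oxidative phosphorylation (camera adjusted p = 0.936) and the immediate early list (0.379), and for complement without the replicate block (0.953) and by fry (0.978); the cause was not tested. Leaving out a pool or the library labelled GFP-negative of pool 3 gave camera adjusted p of 1.23e-05 to 0.755 for cardiomyocyte, 0.171 to 0.994 for endothelium, 0.239 to 0.994 for erythrocyte, 0.825 to 0.994 for neural, 0.325 to 0.862 for complement, 0.00325 to 0.954 for oxidative phosphorylation and 0.745 to 0.994 for immediate early genes, each with a turned direction at least once.

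The F test among pools called 1787 genes, 4007 under library totals, 892 with no filter on low values, and 1068 to 1401 without a pool. Library totals gave 5317 calls for pool 3 minus 1, 2404 for pool 4 minus 1 and 4439 for pool 3 minus 2. Without the library labelled GFP-negative of pool 3, the F test called 1367, and 906 genes were called for pool 3 minus 1 and 1149 for pool 3 minus 2, where leaving out a pool gave up to 1586 and 1739. With no filter, calls were 985, 775, 1104 and 876 for pool 3 minus 1, 4 minus 1, 3 minus 2 and 4 minus 2; more genes were then tested. For pool 4 minus 2 leaving out a pool or that library gave 1134 to 1726. For pool 4 minus 3 the stricter filter gave 1 call and a pseudocount of 5 gave 2. Among the genes named for the pools, 640 results with all libraries stayed past the threshold and 18 did not. With a pool left out, 239 did and 13 did not. These genes were named for their small p in the same F test, so their staying past the threshold is no independent support.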

Other observations

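All tests of explanations in this part were chosen after the results were seen. Outside the fixed lists, the 5 genes with the smallest p in the F test among pools were taken in each direction, from those with a symbol and a mean of at least 10 TPM, by a rule set after the data were seen. Highest in pools 1 and 2 were 2 globin genes listed as HBE1, uncertain because of similar copies. ENSDARG00000097238 had 97.8 to 215 TPM there and was listed at 0 in all 4 libraries of pools 3 and 4, and ENSDARG00000089087 had 1878 to 3731 and 10.5 to 34.7 TPM. PABPC4, which encodes a poly(A)-binding protein, had 169.6 to 291 against 14.2 to 34.1 TPM, the troponin gene tnni4a 301 to 398 against 31.9 to 45.0, and ndufa4b, a gene of the respiratory chain, 158 to 269 against 19.9 to 36.0. Higher in pools 3 and 4 were tm4sf21a with 391 to 876 against 14.5 to 22.6 TPM, the collagen gene col18a1b with 266 to 369 against 3.58 to 7.82, the zinc finger gene glis2a with 103 to 236 against 3.74 to 8.05, the thioredoxin gene txnb with 356 to 877 against 12.5 to 44.7, and the keratin gene krt18b with 409 to 929 against 30.8 to 56.4. Each had an F test adjusted p of at most 0.000894 (limma).

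Marker genes separated the libraries by pool and not by labelled sort, and a lower share of cardiomyocytes alone in pools 3 and 4 is argued against, since it would raise the endothelial markers, whose list median (1 of 37 members also stand in another list) was at most -1.81 on the log2 scale over the 4 contrasts and 4 scalings. One candidate explanation is that library headings were exchanged, which would need 2 libraries of each labelled sort out of place: pairing the libraries of pools 1 and 2 with those of pools 3 and 4 by column order gave a mean correlation of 0.683, a value reached by 2 of 24 pairings. Other exchanges of headings were not tested. Another explanation is that the sort did not separate the cells while the pool labels hold. The libraries of a labelled pool should then resemble each other most. Their mean correlation of 0.859 was reached by 3 of 9 pairings, the highest other being 0.860. A share under 0.05 cannot be had from 9 pairings. An unseparated sort alone would not make pools 3 and 4 differ from pools 1 and 2. Over these contrasts the log2 list median was -3.79 to -3.18 for cardiomyocytes and 2.15 to 2.29 for fibroblasts. These values argue against an unseparated sort as the only cause, without a further difference between the pools. On deviations from the means of the libraries of pools 1 and 2 and of pools 3 and 4, the form run first, the same pairings stood at 3 of 24 and 7 of 9. Exchanged headings, and an unseparated sort joined by a difference between pools, cannot be told apart here, because the correlations differ too little between pairings. Differences in dissociation, sorting or library preparation between pools, and a biological difference between the pools of hearts, were not tested and stay open.

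Whether chance gave the result cannot be weighed on the genes called between the labelled sorts, because a count of 0 is reached by any split: by all 35 splits of the 8 libraries into groups of 4 without the replicate block, and by all 8 splits that part every pair with it, where the highest other called 1. With the block, the labelled split gave 770 genes at an unadjusted p under 0.05, a count reached by 1 of the 8, itself, and the highest other gave 744. It called 5 lists, a number reached by 3 of the 8, and the highest other called 6. A share under 0.05 cannot be had from 8 splits. Without the block, the split of pools 1 and 2 from pools 3 and 4 called 3310 genes, which points to a structure of the samples, and the next highest called 3. That fit counts both libraries of a labelled pool as independent, with 2 pools on each side, and does not show whether the pool labels hold. Without the block, 8 or more lists were called by 16 of the 24 splits that part 2 pairs and by none of the 8 that part all 4.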
